A study of Mus musculus with 5 samples.

How the data were processed

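Poly(A) RNA from 3 trophoblast stem (TS) cell lines and 2 extraembryonic endoderm stem (XEN) cell lines of the mouse was sequenced, with 1 library per line. Per the labels' protocols, cells were grown by the published methods for each cell type, RNA was extracted with a column kit, and standard Illumina libraries were made; whether the libraries keep the strand of the RNA is not given in the sources used here. The genome build was mm10, per the submitters' processing notes. The aligner, the counter and the annotation release are not given in the sources used here. The deposited file of each line lists 36902 mouse Ensembl gene identifiers with 2 values. The first is an RPKM value named cRPKM in the deposited files, a corrected RPKM that divides the reads of a gene by an effective length and by the reads counted on genes, rounded by the authors to 2 decimals. The second is a raw whole-number read count per gene, deposited by the authors without normalization. In 4 of the files 3342 genes have no value, and in the TS OL file 3486. Symbols and coordinates were taken from GENCODE M21, on the same build, which holds 36341 of the identifiers; the other 561 have no symbol.

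The effective length of a gene was read from its count, its cRPKM and the library total, for genes of at least 0.5 cRPKM. It was the same in 4 lines within rounding (a ratio from 0.95 to 1.05), but in TS OL it was below 0.95 of the others for 1312 of 11960 genes (11.0%). Why the lengths differ is not given in the sources used here, and the fold changes of such genes are less certain; 154 of the 1296 such genes tested were called. Genes that overlap a gene on the opposite strand, and members of families of near-identical copies, are uncertain in all lines.

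Groups were taken from the source names in the labels. The comparison of TS with XEN was planned for limma on log2(cRPKM + 1), with edgeR on the counts as the main test if the files held counts, which they did. Counts were tested with edgeR 4.0.16 (quasi-likelihood fit, filterByExpr with a minimum count of 10, TMM normalization, prior count 0.125) in R 4.3.3, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. After the filter 14926 genes were tested, with a common biological coefficient of variation of 0.59. A standard error is the absolute log2 fold change divided by the square root of the F statistic. The values are differences between lines of each type, so p-values measure the spread between lines, each grown and sequenced once. An exact rank-sum test of 3 against 2 lines has 10 splits and cannot give a two-sided p under 0.2, so no such test was run on single values.

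Where a type had no count of a gene, its fold change is a lower bound against a floor of 3 counts over the type. Where it had 1 to 3 counts, the ratio of scaled counts (CPM) is given with its 95% counting interval. Bounds and ratios use counts scaled by TMM-normalized library sizes, not by library totals. The higher type enters as the mean CPM of its lines, so a bound need not hold for each of its lines. Floors and intervals cover counting error only, since reads are not independent molecules.

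There were 24 gene lists, fixed before the data were examined: regulators of trophoblast stem cells and of primitive endoderm, markers of visceral, anterior visceral and parietal endoderm, of spongiotrophoblast, giant cells, syncytiotrophoblast, pluripotent epiblast and fibroblasts, basement membrane, epithelial, mesenchymal, FGF and ERK, TGF-beta and BMP, imprinted, DNA methylation, splicing, endocytic and lysosomal, cell cycle, glycolysis and hypoxia, sex-linked, ribosomal protein and mitochondrially encoded genes. Each list was tested with camera (limma 3.58.1) at a preset inter-gene correlation of 0.01, adjusted over the 24 lists, and again with an estimated correlation and with fry, which tests whether a list's genes move one way on balance without comparing them with other genes. With an estimated correlation, the calls of the trophoblast stem cell regulators, the primitive endoderm regulators and the visceral endoderm products held, and the other calls did not. Genes at 0 counts in one type did not move any list's median when set to their bound.

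The genes named were chosen by a rule fixed before the data were examined: the 6 largest fold changes per direction among called genes with fully separate lines and a mean of at least 5 cRPKM in the higher type; Cdx2, Eomes, Elf5, Gata4, Gata6 and Sox17; of each list up to 3 members with the largest called fold change and up to 2 called in the direction opposite to most of the list, or the 2 highest expressed where none was called; for each line the 3 genes furthest above the nearest other line of the type with at least 10 cRPKM; and every sex-linked reporter. Other list members are named only as exceptions to a count or as examples of values, after their values were seen. Similarity of lines was measured by Pearson's r of log2(cRPKM + 1) and by principal components, with no test.

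The alternatives planned before the data were examined were DESeq2 1.42.0, DESeq2 size factors in edgeR, no filter, a filter of 5 cRPKM in 2 lines, limma on log2(cRPKM + 1) with other pseudocounts (0.1 and 5), filters, scalings, no trend and array weights, and leaving out each line in turn. An offset for the effective length in TS OL, the removal of genes of shorter effective length, and a filter of 1 cRPKM in 2 lines for edgeR were added after the data were examined.

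The fits were tested on simulated data made from these libraries' means and totals. The spread of each gene was edgeR's own dispersion estimate, and genes were drawn independently. The data thus follow edgeR's model, which can favour edgeR over the other fits. Recovery is given over the changed genes that passed the filter. With 200 genes changed before the filter and 14575 genes tested, edgeR recovered 2.04% of genes changed by a log2 fold of 1 and 18.0% of those changed by 2. It recovered 67.3% of those changed by 4 and 90.0% of those changed by 6, with 5 false among 93 calls. With 4000 genes changed before the filter and 14597 tested, it recovered 10.6%, 49.2%, 85.4% and 98.0% of the same sizes, with 72 false among 2461 calls. DESeq2 made 47.3% false calls in the first simulation and 9.06% in the second. Small differences between the types are therefore mostly missed at this number of lines. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.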

Results

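Poly(A) RNA was sequenced from 5 mouse stem cell lines derived from the extraembryonic lineages of the early embryo. Trophoblast stem (TS) cells represent the trophectoderm lineage that builds the fetal part of the placenta, and 3 TS lines (FxL4, JR and OL) were profiled. Extraembryonic endoderm stem (XEN) cells represent the primitive endoderm lineage that lines the yolk sacs, and 2 XEN lines (DIZ6 and JR) were profiled. Each line was sequenced as 1 library, so the replicates of a type are different cell lines and the spread within a type is a spread between lines. The name JR occurs in both types and denotes a different cell line in each. Total gene counts were 73232470 in TS FxL4, 73864814 in TS JR, 74193291 in TS OL, 117382768 in XEN DIZ6 and 67656622 in XEN JR. On library totals, a count of 3 corresponded to between 0.0256 and 0.0443 CPM in a single library. The lower bounds on folds below set the mean of the higher type against 3 counts over all lines of the other, so they need not hold for each line. These bounds and the ratios in CPM below use TMM-normalized library sizes in place of totals. Levels are given as corrected RPKM (cRPKM) as mean ± SD, with n = 3 TS and n = 2 XEN lines. Fold changes come from edgeR's quasi-likelihood test on the counts, are written as log2 (TS over XEN) ± SE, and carry Benjamini-Hochberg adjusted p-values over the 14926 genes tested.

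The transcriptomes of the 2 cell types differed widely. Of the 14926 genes tested, 1524 were higher in TS and 1019 were lower in TS at an adjusted p under 0.05 (edgeR), and 2030 of these differed at least 4-fold. The largest fitted TS-biased changes among clearly expressed genes, whose order depends on the prior count where XEN had no count, were in Bmp8b and Bmp4, which encode secreted bone morphogenetic proteins, the tetraspanin Cd82, the tight-junction gene Cldn3, the matrix metalloproteinase Mmp9 and Wfdc2. Bmp4 was 43.6 ± 12.1 cRPKM in TS with no count in either XEN line, which is at least 4760-fold higher in TS. Cd82 was 53.3 ± 32.4 cRPKM in TS and at least 4645-fold higher, and Cldn3 was 58.4 ± 45.4 cRPKM in TS and at least 3726-fold higher. The largest fitted XEN-biased changes, with the same limit, were in the protease inhibitor Spink1, the aminopeptidase Enpep, the thyroid hormone carrier Ttr, the protease inhibitor A2m, the heparan sulfate 6-O-endosulfatase Sulf1 and the glucuronosyltransferase Ugt2b34. Spink1 reached 377 ± 67.05 cRPKM in XEN with no count in any TS line, which is at least 11526-fold lower in TS. Enpep was 49.3 ± 35.8 cRPKM in XEN against 1 count over the TS lines, a ratio of 50219 in CPM with a counting interval from 9013 to 1983500. The same ratio was 10792 for Sulf1 (2 counts in TS, interval from 2988 to 89113) and 9080 for Ugt2b34 (3 counts in TS, interval from 3107 to 44029).

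**Figure D1:**
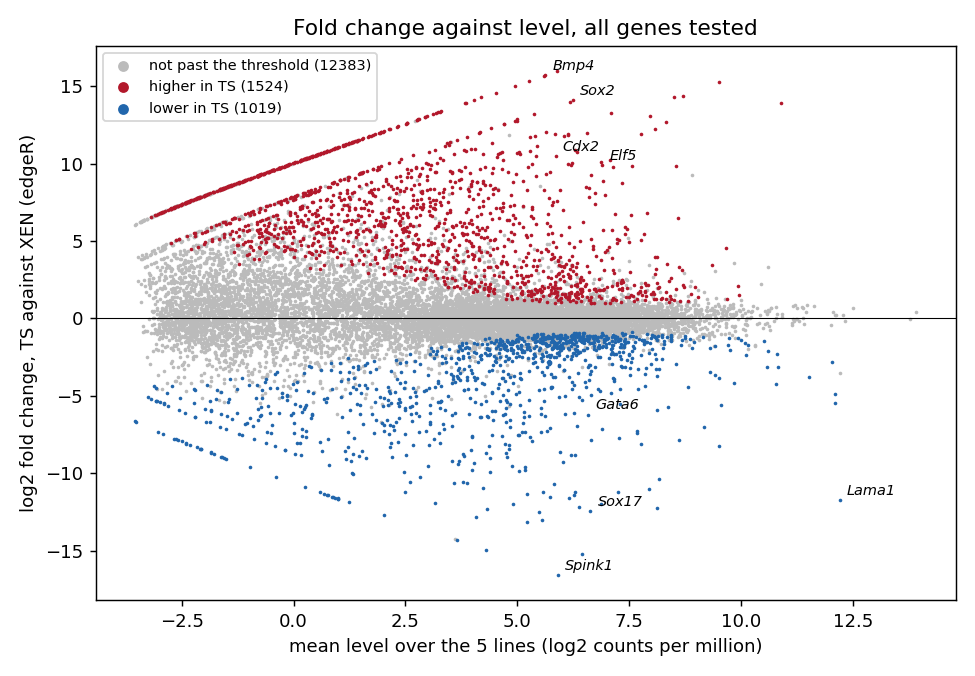
Each point is 1 of the 14926 genes tested, with the mean level over the 5 lines on the x axis (log2 CPM) and the edgeR log2 fold change of TS against XEN on the y axis. The 1524 genes higher in TS and the 1019 lower in TS are coloured, and the straight bands of points at the outer edges are genes with few or no counts in one type, whose fitted fold depends on the prior count.

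Many called genes were close to absent in the other type. No count was found in either XEN line for 305 of the genes higher in TS, and no count in any TS line for 40 of the genes lower in TS. With a mean of at least 5 cRPKM in the higher type, 657 genes were higher and 755 lower in TS. All 1524 genes called higher and 1017 of the 1019 called lower had fully separate line values in the called direction. The test favours such genes, so this adds no support to the calls. Over all tested genes, 51.4% had separate lines in either direction, where a single gene has a 20% chance if the lines are exchangeable. All genes share the same 5 lines, so the 51.4% is descriptive and does not test the types. The share of calls higher in TS was 59.9% with edgeR and 56.5% with limma on log2(cRPKM + 1), but 45.6% with limma after quantile normalization. The counts moved with the lines included: without TS FxL4 they were 838 higher and 523 lower, without TS JR 1052 and 574, without TS OL 1525 and 1093, without XEN DIZ6 512 and 422, and without XEN JR 734 and 478. Among the largest changes, 4 lost their call when some line was left out. Mmp9 stood at 1283 cRPKM in TS OL against 7.34 in FxL4 and 17.7 in JR, and lost its call without XEN DIZ6 (adjusted p = 0.141, edgeR) or XEN JR (0.126). Bmp8b, at least 5739-fold higher in TS, was 0.57 cRPKM in FxL4 against 55.2 in JR and 71.9 in OL, and lost its call without TS JR (adjusted p = 0.0678, edgeR), TS OL (0.0566), XEN DIZ6 (0.101) or XEN JR (0.0849), while its fitted log2 fold change stayed between 15.45 and 16.59. Wfdc2, at least 2969-fold higher in TS, was 6.52 cRPKM in FxL4, 20.4 in JR and 187 in OL. It lost its call without XEN DIZ6 or XEN JR, with fitted log2 fold changes of 14.85 and 15.03. Without TS OL its fitted log2 fold change was 12.76, against 15.02 with all lines. A2m, at least 2423-fold lower in TS, was 12.8 cRPKM in DIZ6 and 0.17 in XEN JR, and its fitted log2 fold change of -14.31 became -8.95 without DIZ6 (adjusted p = 0.104, edgeR). Its adjusted p was also over the threshold without TS FxL4 (0.0651), TS JR (0.0673) or TS OL (0.0575).

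The transcription factors and receptors that maintain trophoblast stem cells were higher in TS. Of the 14 regulators listed before the data were examined, all 14 were tested, 11 were higher in TS and none was lower; adjusted over the list alone, 12 were higher. Cdx2, the caudal-type homeobox factor of the trophectoderm, was 48.1, 22.0 and 68.9 cRPKM in FxL4, JR and OL and 0.02 and 0.04 in the XEN lines (log2 fold change 10.48 ± 0.79, adjusted p = 0.0010, edgeR). Eomes, a T-box factor, was 54.5 ± 28.3 cRPKM in TS and 0.175 ± 0.219 in XEN (log2 fold change 8.12 ± 1.28, adjusted p = 0.0107, edgeR). Elf5, an ETS-family factor, was 96.0 ± 31.2 cRPKM in TS and 0.085 ± 0.021 in XEN (log2 fold change 9.89 ± 0.52, adjusted p = 4.7e-04, edgeR). Sox2 was 66.1 ± 5.00 cRPKM in TS against 1 count over both XEN lines, a ratio of 21791 with a counting interval from 3911 to 860720. Tfap2c was 85.6 ± 9.75 cRPKM in TS and 0.005 ± 0.007 in XEN (log2 fold change 13.24 ± 0.76, adjusted p = 5.1e-04, edgeR). Tead4, Ets2 and Id2 did not pass the test over all genes, and Tead4 was 50.03 ± 10.4 cRPKM in TS and 20.8 ± 8.95 in XEN. The list as a whole was higher in TS than other genes (camera, adjusted p = 3.7e-31), and the call held with an estimated correlation (adjusted p = 0.032). On mm10, Cdx2 lies on the minus strand of chromosome 5 (147300805 to 147307270), Eomes on the plus strand of chromosome 9 (118478212 to 118486132) and Elf5 on the plus strand of chromosome 2 (103411688 to 103450989); the values are over the whole annotated gene.

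Regulators of primitive endoderm showed the opposite pattern. Not all 12 genes of this list are regulators, since it also holds other genes, among them the receptor gene Cubn. Of these 12 genes, all tested, 11 were lower in TS and none was higher, and the count was also 11 adjusted over the list alone. Lrp2 is among the 11, with 0.20 cRPKM in DIZ6 and 15.9 in XEN JR against at most 0.13 in any TS line. Sox17, an SRY-box factor, was 62.5 and 89.5 cRPKM in DIZ6 and XEN JR and at most 0.02 in any TS line (log2 fold change -12.43 ± 0.42, adjusted p = 3.1e-04, edgeR). The zinc-finger factor Gata6 was 70.6 ± 2.16 cRPKM in XEN and between 0.63 and 1.52 in the TS lines (log2 fold change -6.22 ± 0.44, adjusted p = 9.0e-04, edgeR). Gata4 was 227 ± 49.0 cRPKM in XEN and 4.96 ± 2.71 in TS (log2 fold change -5.69 ± 0.59, adjusted p = 0.0029, edgeR). Cubn, which encodes the endocytic receptor cubilin, was 52.1 ± 22.8 cRPKM in XEN and 0.030 ± 0.010 in TS (log2 fold change -11.00 ± 0.53, adjusted p = 4.5e-04, edgeR). Sox7 was 74.1 cRPKM in DIZ6 and 15.0 in XEN JR against 0.130 ± 0.165 in TS (log2 fold change -8.61 ± 1.23, adjusted p = 0.0083, edgeR). Amn was the member that did not pass, with 4.61 cRPKM in DIZ6, 0.61 in XEN JR and 1.11 ± 0.474 in TS. The list was lower in TS (camera, adjusted p = 2.6e-27; adjusted p = 0.032 with an estimated correlation). Sox17 lies on the minus strand of chromosome 1 (4490931 to 4497354), Gata6 on the plus strand of chromosome 18 (11052064 to 11085635) and Gata4 on the minus strand of chromosome 14 (63198922 to 63271692). Sox7 and Gata4 lie on chromosome 14, whose genes had a median 1.59 times as high in DIZ6 as in XEN JR.

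**Figure D2:**
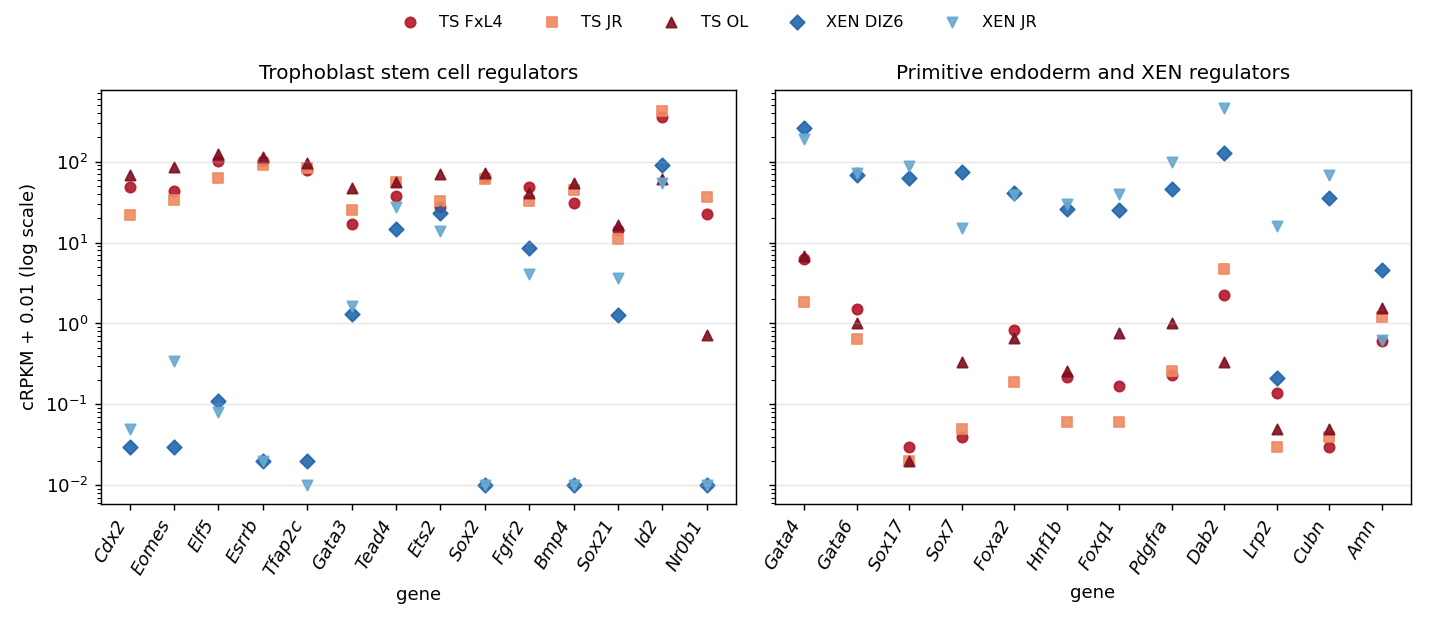
Each point is the cRPKM of 1 gene in 1 line on a log axis, with 0.01 added so that 0 can be drawn, for the 14 trophoblast stem cell regulators (left) and the 12 primitive endoderm and XEN regulators (right). Cdx2, Eomes and Elf5 lie between 22.0 and 124 in the TS lines and at 0.33 or lower in the XEN lines, and Sox17 lies at 62.5 and 89.5 in the XEN lines and at 0.02 or lower in the TS lines.

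Genes of the visceral and parietal endoderm, the 2 cell types that primitive endoderm forms, were both expressed in XEN. Of 15 visceral endoderm products, 12 were tested, 9 were lower in TS and none was higher; adjusted over the list alone, 10 were lower and 1 (Trf) was higher. Ttr was 26.2 and 53.4 cRPKM in the XEN lines with no count in TS, at least 3795-fold lower in TS. Hnf4a, a nuclear receptor of the visceral endoderm, was 12.4 and 9.54 cRPKM in DIZ6 and XEN JR against 2 counts over the TS lines, a ratio of 5805 with a counting interval from 1607 to 47937. Levels of the secreted products in XEN varied widely: Apoe was 131 and 104 cRPKM in DIZ6 and XEN JR, Rbp4 0.11 and 49.0, Afp 1.33 and 0.62, and Apoa1, which was not tested, 0.41 and 0.03. These 4 were chosen after their values were seen. The list was lower in TS (camera, adjusted p = 1.1e-15; adjusted p = 0.032 with an estimated correlation). Of 7 anterior visceral endoderm signals, 4 were tested and 1 passed: Nodal was higher in TS, at 1.31 ± 0.563 cRPKM with no count in XEN, at least 150-fold. Nodal lost its call in 5 limma settings (adjusted p up to 0.129). That list did not pass (camera, adjusted p = 0.68).

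Of 6 parietal endoderm markers, all tested, 5 were lower in TS and none was higher; adjusted over the list alone, all 6 were lower. Plat, tissue plasminogen activator, was 271 ± 79.2 cRPKM in XEN and 0.227 ± 0.122 in TS (log2 fold change -10.39 ± 0.57, adjusted p = 4.9e-04, edgeR). The proteoglycan core gene Srgn was 152 cRPKM in DIZ6 and 53.3 in XEN JR, against 0.263 ± 0.378 in TS (log2 fold change -8.84 ± 1.34, adjusted p = 0.0096, edgeR). Thbd, thrombomodulin, was 74.2 cRPKM in XEN JR but 1.58 in DIZ6, within the range of the TS lines (0.61 to 2.37). Its call rested on XEN JR: the log2 fold change of -5.07 ± 1.37 (adjusted p = 0.048, edgeR) became -0.59 without that line (adjusted p = 0.76), and the call was also lost without TS FxL4 (0.134), TS JR (0.136) or TS OL (0.0759). The list was lower in TS (camera, adjusted p = 2.6e-07), a call that was lost with an estimated correlation (adjusted p = 0.068).

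Some laminin and other basement membrane genes were highly expressed in XEN, while the laminin genes Lama5 (10.9 ± 11.9 cRPKM) and Lamb2 (32.8 ± 3.21) were at lower levels there. Of 12 components, all tested, 5 were lower in TS and none was higher; adjusted over the list alone, 9 were lower. Lama1, the laminin alpha 1 chain, was 886 and 1463 cRPKM in DIZ6 and XEN JR and 0.383 ± 0.023 in TS (log2 fold change -11.73 ± 0.57, adjusted p = 4.5e-04, edgeR). Lamb1 was 1736 ± 444 cRPKM in XEN and 44.0 ± 12.6 in TS (log2 fold change -5.44 ± 0.48, adjusted p = 0.0018, edgeR). Nid2, which encodes the laminin-binding nidogen 2, was 351 ± 143 cRPKM in XEN and 8.33 ± 5.21 in TS (log2 fold change -5.57 ± 0.67, adjusted p = 0.0048, edgeR); it lies on chromosome 14 and has a shorter effective length in the TS OL file. The collagen IV gene Col4a1, named after its values were seen, did not pass (adjusted p = 0.081, edgeR) and differed between the XEN lines, with 95.3 cRPKM in DIZ6 and 2942 in XEN JR against 145 ± 48.2 in TS. The list was lower in TS (camera, adjusted p = 8.2e-12), but not with an estimated correlation (adjusted p = 0.14). Lama1 lies on the plus strand of chromosome 17 (67697259 to 67822647).

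Endocytic and lysosomal genes were in part higher in XEN. Of 16 genes, all tested, 6 were lower in TS and none was higher; adjusted over the list alone, 7 were lower. The lysosomal protease genes among them were Ctsh, at 148 ± 137 cRPKM in XEN and 0.743 ± 0.711 in TS (log2 fold change -7.86 ± 1.21, adjusted p = 0.0101, edgeR), Lgmn (log2 fold change -4.18 ± 0.39, adjusted p = 0.0021, edgeR) and Ctsl (log2 fold change -2.39 ± 0.33, adjusted p = 0.0073, edgeR). Lgmn was 1026 ± 308 cRPKM in XEN and 63.6 ± 19.7 in TS, and Ctsl was 1044 ± 246 in XEN and 222 ± 44.7 in TS. The list was lower in TS (camera, adjusted p = 1.4e-04), but not with an estimated correlation (adjusted p = 0.53).

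**Figure D3:**
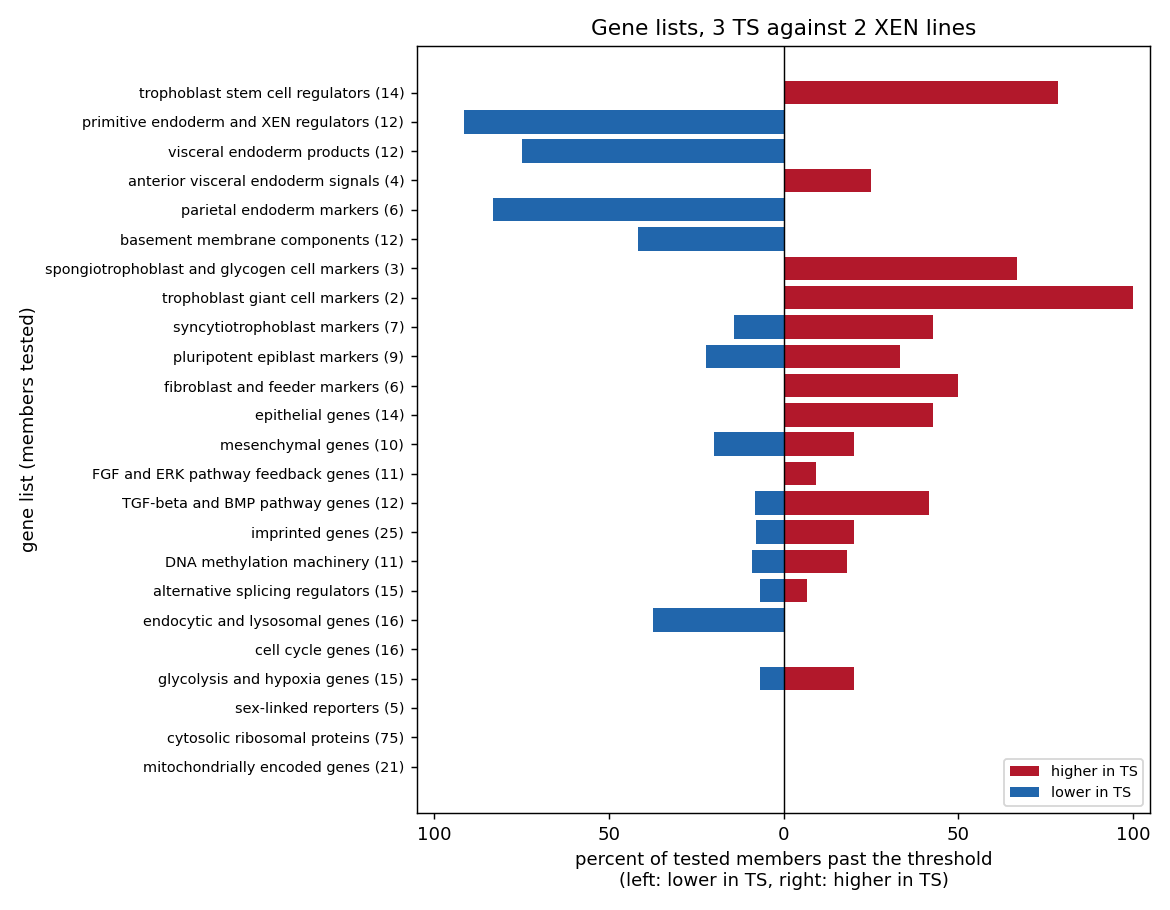
Bars give the percent of each list's tested members that passed the edgeR threshold, with members lower in TS to the left of 0 and members higher in TS to the right, and the number of members tested in parentheses. Trophoblast stem cell regulators pass to the right (11 of 14), and primitive endoderm regulators (11 of 12) and visceral endoderm products (9 of 12) pass to the left.

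Markers of differentiated trophoblast ranged from absent to highly expressed. Flt1 was 6.20 to 12.3 cRPKM over the 5 lines, and Slc16a3 and Ly6e were 132 and 46.9 cRPKM on average in TS; these 3 did not pass the test and were chosen after their values were seen. Of 8 trophoblast giant cell markers, 2 were tested and both were higher in TS (camera, adjusted p = 5.9e-04; adjusted p = 0.30 with an estimated correlation). Hand1, a basic helix-loop-helix factor, was 401 ± 271 cRPKM in TS and 0.020 ± 0.028 in XEN (log2 fold change 14.36 ± 1.37, adjusted p = 0.0022, edgeR), and the other was Mmp9. The placental lactogen genes Prl3d2, Prl3d3 and Prl3b1 had a cRPKM of 0 in all 5 lines, and Prl3d1 and Prl2c2 had no value. Of 6 spongiotrophoblast and glycogen cell markers, 3 were tested and 2 were higher in TS, with no call for the list (camera, adjusted p = 0.26). Ascl2 was 2.01 ± 1.90 cRPKM in TS against 1 count over the XEN lines, a ratio of 525 with a counting interval from 94.1 to 20718, and Pcdh12 was 3.01 ± 4.29, Pcdh12 with 7.96 in OL against 0.60 in FxL4 and 0.46 in JR. Ascl2 lost its call without XEN DIZ6 (adjusted p = 0.0822, edgeR) or XEN JR (0.091), as did Pcdh12 (0.128 and 0.11). The spongiotrophoblast marker Tpbpa was at most 0.05 cRPKM in any line. Of 8 syncytiotrophoblast markers, 7 were tested, 3 were higher and 1 was lower in TS (camera, adjusted p = 0.079). The homeobox gene Dlx3 was 1.91 ± 0.516 cRPKM in TS against 1 count over the XEN lines, a ratio of 821 with a counting interval from 147 to 32415. Gcm1 was 0.16, 0.39 and 0.36 cRPKM and Cebpa 0.54, 0.18 and 4.34 in FxL4, TS JR and OL. The fitted log2 fold change of Cebpa (1.69 ± 2.30 cRPKM in TS) fell from 11.30 to 9.195 without TS OL. Neither gene had a count in XEN (Gcm1 at least 32.3-fold and Cebpa at least 226-fold higher in TS). Both lost their calls without XEN DIZ6 (Gcm1 0.133 and Cebpa 0.119, adjusted p, edgeR) or XEN JR (0.105 and 0.0972), and Cebpa also without TS FxL4 (0.0622). The monocarboxylate transporter Slc16a1 went the other way, at 81.6 ± 15.4 cRPKM in TS and 257 ± 68.8 in XEN (log2 fold change -1.78 ± 0.35, adjusted p = 0.020, edgeR). It lost its call without TS JR (adjusted p = 0.058), XEN DIZ6 (0.0505) or XEN JR (0.105).

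Pluripotency-associated genes went in both directions. Of 12 markers, 9 were tested, 3 were higher and 2 were lower in TS (camera, adjusted p = 0.090). Pou5f1, which encodes the core pluripotency factor OCT4, was at most 0.17 cRPKM in every line. Utf1 was 111 ± 93.6 cRPKM in TS against 1 count over the XEN lines, a ratio of 20920 with a counting interval from 3755 to 826290. Dppa4 was 64.5 ± 28.5 cRPKM in TS and 0.180 ± 0.014 in XEN (log2 fold change 8.32 ± 0.55, adjusted p = 7.1e-04, edgeR). Klf4, a Krüppel-like factor, was higher in XEN, at 35.7 ± 6.92 cRPKM against 1.64 ± 0.672 in TS (log2 fold change -4.57 ± 0.44, adjusted p = 0.0023, edgeR). The RNA-binding protein gene Lin28a was 188 ± 41.5 cRPKM in XEN and 63.2 ± 25.7 in TS (log2 fold change -1.71 ± 0.40, adjusted p = 0.034, edgeR). Lin28a lost its call without TS JR (adjusted p = 0.0938), TS OL (0.058), XEN DIZ6 (0.0869) or XEN JR (0.15).

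Some epithelial junction genes and the keratin gene Krt7 were higher in TS, and mesenchymal genes went both ways. Of 14 epithelial genes, all tested, 6 were higher in TS and none was lower; adjusted over the list alone, 7 were higher and 1 was lower. Cldn4, a claudin, was 375 ± 337 cRPKM in TS and 0.015 ± 0.007 in XEN (log2 fold change 14.27 ± 1.36, adjusted p = 0.0022, edgeR). Krt7 was 61.6 ± 61.8 cRPKM in TS and 0.040 ± 0.028 in XEN (log2 fold change 10.26 ± 1.27, adjusted p = 0.0053, edgeR). Esrp1, an epithelial splicing regulator, was 9.23 ± 6.63 cRPKM in TS and 0.055 ± 0.049 in XEN (log2 fold change 7.25 ± 1.03, adjusted p = 0.0080, edgeR). Each of these 3 genes was highest in TS OL, at 749 cRPKM for Cldn4, 133 for Krt7 and 16.6 for Esrp1. The epithelial list was higher in TS (camera, adjusted p = 4.9e-04), but not with an estimated correlation (adjusted p = 0.58). Of 10 mesenchymal genes, all tested, 2 were higher and 2 were lower in TS (camera, adjusted p = 0.91). N-cadherin (Cdh2) was 2.24 ± 1.45 cRPKM in TS and 0.010 in both XEN lines (log2 fold change 7.65 ± 1.12, adjusted p = 0.0088, edgeR), a call that was lost in 6 limma settings (adjusted p up to 0.184). Zeb2, a repressor of E-cadherin, was 1.88 ± 0.028 cRPKM in XEN and 0.087 ± 0.042 in TS (log2 fold change -4.59 ± 0.64, adjusted p = 0.0077, edgeR). The other pair was Tgfbi, at 0.347 ± 0.237 cRPKM in TS with no count in XEN (at least 52.3-fold higher), and Itga5, at 90.2 ± 3.56 in XEN and 33.7 ± 12.7 in TS. Tgfbi lost its call without TS FxL4 (adjusted p = 0.0566, edgeR), XEN DIZ6 (0.118) or XEN JR (0.0943), and Itga5 without TS FxL4 (0.0614), TS JR (0.0617), XEN DIZ6 (0.0764) or XEN JR (0.0733). Of 13 fibroblast and feeder cell markers, 6 were tested and 3 were higher in TS (camera, adjusted p = 0.090; fry, adjusted p = 0.037), all of them at low levels. Twist2 was 1.24 ± 0.462 cRPKM in TS with no count in XEN (at least 67.4-fold higher), and Thy1 was 1.39 ± 0.979 against 2 counts in XEN, a ratio of 192 with a counting interval from 53.1 to 1584. Col1a1 was 0.260 ± 0.217 cRPKM in TS, while the abundant fibroblast collagen genes Col1a2 and Col3a1 were at most 0.02 in any line. Without XEN DIZ6 or XEN JR the adjusted p (edgeR) of Twist2 was 0.070 and 0.0511, of Thy1 0.0831 and 0.11, and of Col1a1 0.131 and 0.138. Thy1 also lost its call without TS FxL4 (0.0629), and Twist2 has a shorter effective length in the TS OL file.

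Signalling genes differed in both directions, and neither signalling list passed with edgeR on all lines and filtered genes. Of 14 TGF-beta and BMP pathway genes, 12 were tested, 5 were higher and 1 was lower in TS (camera, adjusted p = 0.65), and adjusted over the list alone 5 were higher and 2 lower. Besides Bmp8b, Bmp7 was 7.78 ± 6.17 cRPKM in TS and 0.010 in both XEN lines (log2 fold change 9.42, adjusted p = 0.0058, edgeR). Fst, which encodes the activin antagonist follistatin, was 108 cRPKM in DIZ6 and 465 in XEN JR against 0.067 ± 0.035 in TS (log2 fold change -12.21 ± 0.95, adjusted p = 0.0011, edgeR). Of 11 feedback genes of the FGF and ERK pathway, all tested, 1 was higher in TS (camera, adjusted p = 0.10), and none passed adjusted over the list alone. That gene was Spred2, at 29.5 ± 4.12 cRPKM in TS and 9.98 and 13.94 in the XEN lines (log2 fold change 1.17 ± 0.30, adjusted p = 0.044, edgeR). Spred2 lost its call without TS FxL4 (adjusted p = 0.108), TS JR (0.092), XEN DIZ6 (0.291) or XEN JR (0.145). The FGF and ERK list passed in 10 of 19 other settings, among them limma on log2(cRPKM + 1) (camera, adjusted p = 0.025) and edgeR without XEN DIZ6 (0.0021), with a range from 0.0021 to 0.69 over the settings.

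Imprinted genes, DNA methylation genes and splicing regulators were not shifted as lists. Of 29 imprinted genes, 25 were tested, 5 were higher and 2 were lower in TS (camera, adjusted p = 0.91), and adjusted over the list alone 7 were higher and 3 lower. Igf2, a fetal growth factor, was 947 ± 927 cRPKM in TS and 0.055 ± 0.035 in XEN (log2 fold change 13.91 ± 2.40, adjusted p = 0.014, edgeR; 0.067 without XEN DIZ6). Slc38a4, an amino acid transporter, was 116 ± 102 cRPKM in TS and 0.025 ± 0.035 in XEN (log2 fold change 12.24 ± 1.65, adjusted p = 0.0070, edgeR). Cdkn1c, a cell cycle inhibitor with a shorter effective length in the TS OL file, was 73.8 and 165 cRPKM in FxL4 and OL but 0.07 in TS JR. It was 0.015 ± 0.007 in XEN (adjusted p = 0.047, edgeR; 0.203 without XEN DIZ6 and 0.166 without XEN JR), with no value from the fits without FxL4 or without OL. Impact was higher in XEN, at 48.8 ± 13.9 cRPKM against 2.37 ± 1.38 in TS (log2 fold change -4.54 ± 0.57, adjusted p = 0.0056, edgeR), as was Smoc1, at 49.1 ± 3.66 against 2.76 ± 1.92 (log2 fold change -4.32 ± 0.75, adjusted p = 0.014, edgeR). Of 11 DNA methylation genes, all tested, 2 were higher and 1 was lower in TS (camera, adjusted p = 0.91). Dnmt3l, a cofactor of the de novo methyltransferases, was 29.2 ± 27.4 cRPKM in TS and 0.165 ± 0.049 in XEN (log2 fold change 7.27 ± 0.98, adjusted p = 0.0070, edgeR). Dnmt3b was 83.9 ± 12.02 cRPKM in TS and 32.7 ± 2.94 in XEN, and Mbd3 was 41.6 ± 2.23 in TS and 72.4 ± 9.08 in XEN. Dnmt3b lost its call (adjusted p = 0.038, edgeR) without TS FxL4 (0.0921), TS JR (0.0853), XEN DIZ6 (0.242) or XEN JR (0.196). Mbd3 lost its call (adjusted p = 0.048, edgeR) without TS FxL4 (0.122), TS JR (0.0796), TS OL (0.0713), XEN DIZ6 (0.285) or XEN JR (0.145). Of 17 splicing regulators, 15 were tested, 1 was higher and 1 was lower in TS (camera, adjusted p = 0.91). Khdrbs3 was 7.21 ± 1.84 cRPKM in TS against 2 counts over the XEN lines, a ratio of 1121 with a counting interval from 310 to 9256. Celf2 was 4.36 ± 1.51 cRPKM in XEN and 0.703 ± 0.284 in TS (log2 fold change -2.79 ± 0.51, adjusted p = 0.016, edgeR; 0.0907 without XEN DIZ6). The DNA methylation list had a median log2 fold change of -0.24 and a mean of 0.45, and the splicing list a median of 0.09 and a mean of 0.59 with a downward camera direction.

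Housekeeping groups gave few calls. Of 15 glycolysis and hypoxia genes, all tested, 3 were higher and 1 was lower in TS (camera, adjusted p = 0.54), with a median log2 fold change of -0.42 and a mean of 0.84. Pfkp, the platelet-type phosphofructokinase, was 70.2 ± 16.6 cRPKM in TS and 0.145 ± 0.092 in XEN (log2 fold change 8.74 ± 0.63, adjusted p = 9.6e-04, edgeR); it has a shorter effective length in the TS OL file. The glucose transporters went in opposite directions, with Slc2a1 at 433 ± 71.0 cRPKM in TS and 134 ± 36.8 in XEN, and Slc2a3 at 134 ± 137 in TS and 1590 ± 794 in XEN. Slc2a1 (adjusted p = 0.036, edgeR) lost its call without TS FxL4 (0.0878), TS JR (0.0759), XEN DIZ6 (0.104) or XEN JR (0.233), and Slc2a3 (adjusted p = 0.037) without TS FxL4 (0.0552), TS JR (0.115) or XEN DIZ6 (0.118). None of the 16 cell cycle genes passed (camera, adjusted p = 0.68), and Top2a was 228 ± 39.1 cRPKM in TS and 140 ± 41.1 in XEN. None of 75 tested ribosomal protein genes passed, although the list as a whole leaned towards TS (median log2 fold change 0.51; camera, adjusted p = 0.049; adjusted p = 0.90 with an estimated correlation). That call was lost without TS FxL4 (adjusted p = 0.092) and without XEN JR (0.91). Rps24 was 3247 ± 460 cRPKM in TS and 3832 ± 2822 in XEN, and Rpl19 was 2976 ± 904 in TS and 2203 ± 212 in XEN. None of 21 tested mitochondrially encoded genes passed (camera, adjusted p = 0.87), with mt-Co1 at 9551 ± 3377 cRPKM in TS and 8997 ± 2978 in XEN and mt-Co2 at 7741 ± 964 and 5999 ± 2770.

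Lines of a type resembled each other more than lines of the other type. Across 13093 genes within a pair of lines, Pearson's r of log2(cRPKM + 1) was 0.955 between FxL4 and TS JR, 0.889 between FxL4 and OL, 0.901 between TS JR and OL, and 0.947 between the XEN lines, against 0.757 to 0.830 between types. Genes are not independent replicates, so these values describe the libraries. The first principal component held 63.8% of the variance and separated the types, and the second held 20.01% and separated TS OL from the other TS lines. Genes at least 4-fold apart with at least 10 cRPKM in the higher line numbered 108 between FxL4 and TS JR, 412 between FxL4 and OL, 365 between TS JR and OL, and 188 between the XEN lines. The TS OL library also stood apart in the genes with reads, with 21765 against 17168 to 18583 in the other lines.

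Differences between single lines have no replicate check. In FxL4 the genes furthest above the nearest other TS line were the predicted microRNA gene Gm49346 (41.0 cRPKM against 0), Apol8 (30.9 against at most 0.10) and the ubiquitin-like gene Ubd (17.8 against at most 0.06). In TS JR they were Xlr4a (36.8), Gm25442 (27.1) and Gm12666 (22.8), each at 0 in the other TS lines. Gm25442 is also annotated as a microRNA gene. In FxL4, 3 counts (0.0410 CPM) over an effective length of a single base would give the value of Gm49346. The cRPKM of these microRNA genes can thus rest on very few reads. In TS OL they were the mitochondrial tRNA genes mt-Ts1 (1964) and mt-Te (368), both at 0 in the other TS lines, and the ribosomal RNA gene CT010467.1 (422 against at most 0.56). Both tRNA genes lie on the mitochondrial light strand, whose genes together were 29.6-fold higher in TS OL than the median of the other lines, and CT010467.1 has a shorter effective length in the TS OL file. In DIZ6 they were Xlr4a (71.8 against 1.06 in XEN JR), the death receptor gene Tnfrsf10b on chromosome 14 (35.3 against 0.06) and the Y-linked Eif2s3y (28.9 against 0). In XEN JR they were the collagen chaperone gene Fkbp10 (134 against 0.11 in DIZ6), the keratin gene Krt19 (145 against 1.01) and Gpx3 (69.4 against 0.30), which all lie on chromosome 11. Xlr4a belongs to a family of near-identical copies, so its reads are uncertain.

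Imprinted genes varied between the TS lines. Of the genes known for maternal expression, Igf2r was 44.2 and 78.6 cRPKM in FxL4 and OL and 0.85 in TS JR. Phlda2 was 37.7 and 86.8 in FxL4 and OL and 0 in TS JR. Grb10 (186, 65.4 and 28.5 in FxL4, TS JR and OL), H19 (0.63, 1.68 and 51.5), Meg3 (0, 0.80 and 1.39) and Zim1 (0.14, 0.27 and 0.59), which are also maternally expressed, were not lowest in TS JR. Of the genes known for paternal expression, Peg10 was 593 cRPKM in TS JR against 141 and 218 in FxL4 and OL, and Mest was 199 against 71.0 and 16.2. Igf2, which is also paternally expressed, was 24.0 in TS JR against 938 and 1878. These genes other than Igf2 and Cdkn1c were named after their values were seen.

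**Figure D4:**
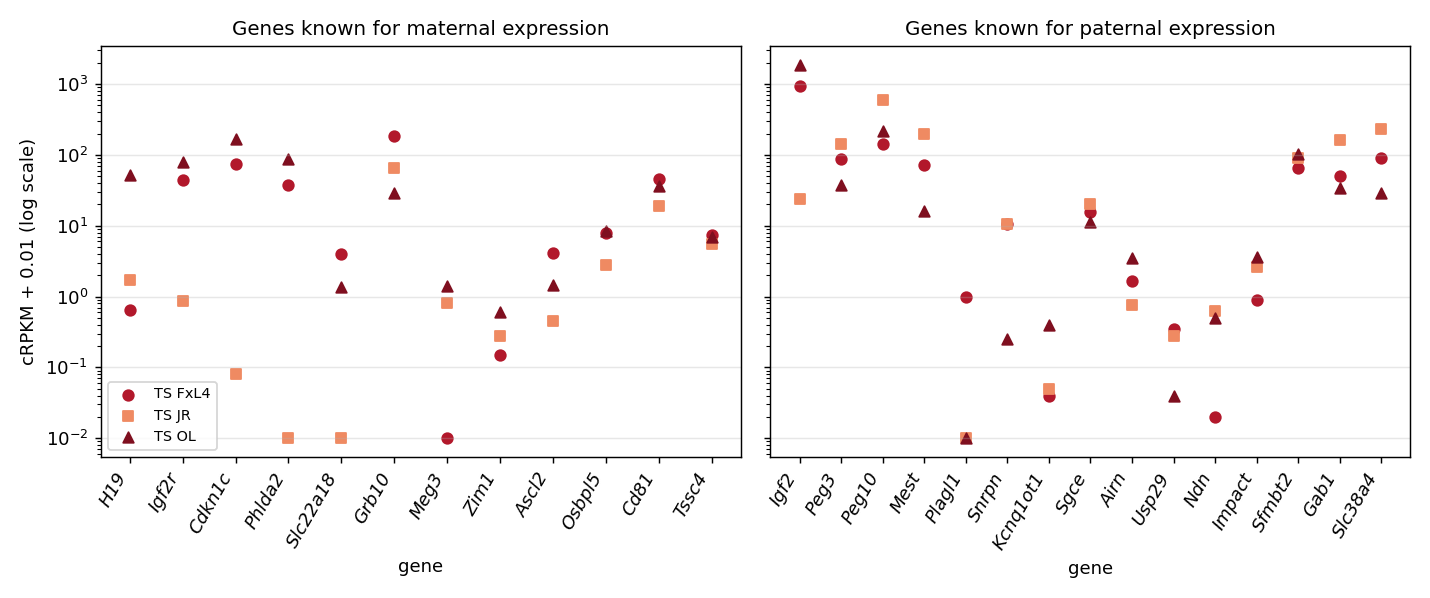
Each point is the cRPKM of 1 imprinted gene in 1 TS line on a log axis, with 0.01 added so that 0 can be drawn, for genes known for maternal (left) and paternal (right) expression. In TS JR, Igf2r (0.85), Cdkn1c (0.07) and Phlda2 (0) lie below both other TS lines, and Peg10 (593) and Mest (199) lie above them.

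Sex-linked reporters differed between lines of the same type, and none of the 5 tested passed (camera for the list, adjusted p = 0.93). The Y-linked Ddx3y was 15.4 cRPKM in FxL4 and 16.4 in DIZ6, and at most 0.01 in the other 3 lines. Uty was 4.78 in FxL4, 3.95 in DIZ6 and 0 elsewhere, and Eif2s3y was 1.25 in FxL4, 28.9 in DIZ6 and at most 0.02 elsewhere. Kdm5d was between 0.02 and 0.08 in every line. Xist, the RNA that coats the inactive X chromosome, was 184 cRPKM in TS OL and 7.26 in TS JR, and at most 0.13 in FxL4 and both XEN lines. It passed without TS FxL4 (log2 fold change 9.87, adjusted p = 0.0433, edgeR), but not with all lines (adjusted p = 0.109). Its antisense gene Tsix was 0.13 in OL and 0 elsewhere, and Xist has a shorter effective length in the TS OL file.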

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

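Leaving out lines, every pseudocount, filter and scaling of limma, DESeq2, its size factors and no filter were chosen before the data were examined; the effective-length offset, the removal of genes of shorter effective length in TS OL and the 1 cRPKM filter for edgeR were chosen after seeing the data. No call of the main edgeR test had the opposite sign in the calls of any of the 21 other fits, but the counts moved. The 1524 genes higher in TS became 2843 with DESeq2, 623 with edgeR at 5 cRPKM, and with limma 982, or 708 at pseudocount 5, 294 with no filter, 827 at 5 cRPKM, 932 with TMM-like scaling, 759 with quantile normalization and 985 with no trend; leaving out a line gave 512 to 1525. The 1019 lower genes became 1634 with DESeq2, 601 with edgeR at 5 cRPKM, and 352 and 660 with limma with no filter and at 5 cRPKM; leaving out a line gave 422 to 1093. The 2030 genes at least 4-fold apart became 3302 with DESeq2, 778 and 1339 with edgeR at 5 and 1 cRPKM, and with limma 901, or 359 at pseudocount 5, 396 with no filter, 812 at 5 cRPKM, 918 with TMM-like scaling, 854 with quantile normalization, 894 with no trend and 996 with array weights; leaving out a line gave 903 to 2095. The cRPKM filters test fewer genes (8762 and 11557 against 14926), a larger pseudocount shrinks the folds of low genes by construction, and leaving out a line leaves fewer samples; for the other settings the cause was not tested. Where 1 XEN line is left, it is assumed to vary like the TS lines. The offset gave 1539 higher and 1024 lower genes, and kept 2531 of the 2543 main calls. Among the 1296 tested genes of shorter length it lost 11 calls and gained 7. Removing all genes of shorter length and filtering again (13643 genes tested) gave 1469 and 982. Quantile normalization moved the median log2 fold change of all genes from 0.10 to -0.03. Of the called named genes, 11 of 69 lost their call without TS FxL4, 11 of 70 without TS JR, 5 of 69 without TS OL, 23 of 70 without XEN DIZ6 and 20 of 70 without XEN JR; 32 lost it with limma without a filter. Of the genes that kept their call without any 1 line, Cdh2 lost it in 6 other settings, Nodal in 5, Dlx3 in 3, Esrp1 and Bmp7 in 2, and Sox7, Krt7, Smoc1 and Dnmt3l in 1 (adjusted p up to 0.184, 0.129, 0.0693, 0.103, 0.146, 0.0541, 0.0558, 0.0545 and 0.0677 in that order). The genes that changed sign were not called in any of these fits: Rps24 (0.030 with array weights), Rpl19 (-0.027 with quantile normalization), mt-Co2 (-0.00824 with quantile normalization) and mt-Co1 (0.011 with edgeR at 5 cRPKM, 0.056 with limma at every pseudocount, at every filter and with no trend), and when lines were left out Ccnb1 (-0.021 to 0.22), Eif2s3y (-6.24 to 8.80), Rps24 (-1.03 to 0.68), mt-Co1 (-0.42 to 0.32), mt-Co2 (-0.25 to 0.78), Ddx3y (-1.81 to 13.73), Kdm5d (-0.38 to 0.58) and Uty (-1.44 to 12.20). Of the list calls, those of the trophoblast stem cell regulators, primitive endoderm regulators and visceral endoderm products held in all 19 settings, and those of parietal endoderm and basement membrane genes in all but the estimated correlation. The giant cell list was lost in 4 settings (adjusted p up to 0.30), epithelial and endocytic lists in 2 (up to 0.58 and 0.53) and the ribosomal list in 5 (up to 0.91); the FGF and ERK list, not called with edgeR on all lines and filtered genes, passed in 10 of 19 settings (adjusted p from 0.0021 to 0.69 over them), the pluripotent list in 4 (from 0.012 to 0.55), the syncytiotrophoblast list in 3 (from 1.4e-04 to 0.89) and the fibroblast list in 3 of 17 (from 0.037 to 0.74). With a pseudocount of 0.1 the lowest r within a type was 0.846 and the highest between types 0.778, and at 30 cRPKM the genes 4-fold apart numbered 43 between FxL4 and TS JR, 201 between FxL4 and OL, 167 between TS JR and OL and 62 between the XEN lines. No paired analysis was possible because the replicate numbers were given in accession order and the name JR, the only one shared, denotes a different cell line in each type.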

Other observations

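The tests on shortened genes and on mitochondrial strands in TS OL, on the chromosome 7 neighbours and the expressed allele in TS JR, and on chromosome 14 copy number were chosen only after the result was seen; the other tests below had their predictions written before their values were computed.

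Wnt ligand genes were among the genes higher in TS that no list held. Wnt7b was between 131 and 134 cRPKM in the TS lines and 12.3 to 13.4 in the XEN lines (log2 fold change 3.22 ± 0.29, adjusted p = 0.0019, edgeR), and Wnt6 was 22.1 to 37.7 against 0.04 to 0.14 (log2 fold change 8.27 ± 0.80, adjusted p = 0.0023, edgeR). Wnt4 went the other way, at 3.14 and 1.65 cRPKM in XEN and at most 0.37 in TS (adjusted p = 0.040, edgeR). Of 230 gene families defined by symbol after the data were examined, the Wnt family (6 of 13 tested genes higher in TS and 1 lower) and the Rgs family of G protein regulators (7 of 16 higher) had the lowest p (camera, adjusted p = 0.043 for both; adjusted p = 0.998 with an estimated correlation). Rgs12 was 5.54 to 6.92 cRPKM in TS and 0.50 to 0.62 in XEN (log2 fold change 3.33 ± 0.41, adjusted p = 0.0053, edgeR). These genes were chosen after their values were seen.

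The XEN lines differed in several genes, given here as untested values of DIZ6 and XEN JR in cRPKM: Col4a1 95.3 and 2942, Col4a2 41.4 and 601, Lrp2 0.20 and 15.9, Rbp4 0.11 and 49.0, and Slc16a3 0 and 18.9. These genes were also chosen after their values were seen.

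TS OL had reads on more genes than the other lines and shorter effective lengths. As a hypothesis, its reads were counted on both strands and those of the other lines on 1 strand: 92.5% of its shortened genes have an exon of an opposite-strand gene, against 23.5% of the other genes, and light-strand mitochondrial genes were 29.6-fold over the median of the other lines, against 1.08-fold for the heavy strand. The genes detected in TS OL alone overlapped an opposite-strand exon in 27.9% of cases, against 15.7% to 20.1% for the other lines, a value between the bounds that had been set, which cannot tell. Depth did not explain the pattern, since after thinning to the smallest total TS OL still had 1.17 times the genes with reads of the next line. The values are consistent with a difference in library or counting, and the sources used here do not state it.

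In TS JR, 10 of 11 maternally expressed imprinted genes measured were below the other TS lines on average, Grb10 and Tssc4 only slightly. Of the list fixed beforehand, H19, Grb10, Meg3 and Zim1 were not lowest in TS JR. Of the 11 genes, 8 lie in 1 cluster on distal chromosome 7, of which H19 was lower in FxL4 (0.63 cRPKM) than in TS JR (1.68). A loss of the whole region did not explain the low values, since the median log2 difference of 16 non-imprinted neighbours was -0.28, although the lowest of them was at -3.56. Scaling did not explain the low values either, with a median of 0.0043 over expressed genes. As a hypothesis, the change goes by the expressed allele. The median log2 difference of the 11 genes was -1.30, at percentile 0 of 10000 random lists, and that of 11 paternally expressed genes was 1.28, at percentile 100. The median of -1.30 is the value of Ascl2. Ascl2, Osbpl5 (-1.26), Cd81 (-1.04) and Tssc4 (-0.30) were not in the imprinted list fixed beforehand, and all lie in the chromosome 7 cluster. The maternal percentile is thus that of a list enlarged from this cluster, and it cannot tell the allele from the cluster. Each line is set against the other TS lines, and the maternal list was at percentile 100 in FxL4 and 98.0 in OL and the paternal list at 0.23 in OL. Of the paternally expressed genes, Peg10 (1.75), Mest (2.51) and Sgce (0.56) lie on chromosome 6. Genes of that chromosome had a median log2 difference of 0.25 in TS JR, with 72.8% above 0. The maternal percentile rests mostly on the 1 cluster, where the paternally expressed Igf2 was low too (-5.73), and of the 3 genes elsewhere Igf2r was low (-5.02) and Grb10 (-0.16) and Meg3 (0.22) were not, so a change confined to that cluster and Igf2r stays open, with alleles assigned from background knowledge after the values were seen and none measured.

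Genes of chromosome 14 were higher in DIZ6 than in XEN JR, with a median log2 difference of 0.67 over 216 genes, 94.0% of them above 0, the largest shift of any chromosome between these lines. None of 2000 random gene sets was as far, but this also held for chromosomes 1 (-0.20), 11 (-0.14), 12 (-0.42), 17 (0.11), 19 (-0.28) and X (0.18). GC content and transcript length did not explain it, as the median was 0.69 after regression on both, nor did a single stretch, as the lowest median of 4 consecutive stretches of 54 genes was 0.59. A difference in chromosome 14 copy number remains an untested hypothesis, since its range was written after the median of 0.67 was seen and DNA was not measured. Against the mean of the TS lines the chromosome 14 median was 0.47 in DIZ6 and -0.20 in XEN JR, and other chromosomes were as far from TS, such as 8 (0.48 and 0.38), 16 (0.40 and 0.36) and 19 (0.30 and 0.61).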
